A study of Homo sapiens with 4 samples.

How the data were processed

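Polyadenylated RNA was sequenced from 2 human oral squamous carcinoma cell lines, CAL27 and SCC15, each grown with the solvent DMSO or with 10 µM 5-aza-2'-deoxycytidine (decitabine) for 48 h. Decitabine is a cytidine analogue that is incorporated into DNA and traps DNA methyltransferases, so that methylation is lost as cells divide. Each combination of cell line and treatment had 1 library, 4 in all. Per the labels' protocols, RNA was extracted with Trizol from cells in multiwell plates and libraries were made with the NEBNext Ultra RNA kit. That kit starts from fragmented RNA and amplifies by PCR, without molecular identifiers in the labels, so counting intervals and floors given here cover counting error only.

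The deposited table held whole-number read counts per gene for the 4 libraries, and also FPKM values that the authors computed from those counts. Per the submitters' processing notes, HISAT2, HTSeq 0.13.5 and the genome build GRCh38 were used. Aligner settings, the annotation release and the strand setting of the counting are not given in the sources used here. Without a known strand setting, reads of a gene and of an antisense or overlapping partner cannot be told apart, which concerns H19, HOTAIRM1 and MIR222HG among the genes named. Reads of near-identical families (MAGE, NPIP, GOLGA8, metallothionein, HLA and keratin genes, and mitochondrial genes with their nuclear copies) may also be split or lost in counting, and their values are uncertain. The table held 51103 genes, and every gene had a name. All 51103 identifiers were found in GENCODE release 29, 51091 of them with the same name, and 51 names were carried by more than 1 identifier. Coordinates, and the GC content of each gene's longest transcript, were taken from that release on GRCh38. The gene lengths implied by count and FPKM were constant across libraries (largest relative spread 5.1e-14). The FPKM were used in alternatives alone.

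Library totals were 14524461 reads for CAL27 with DMSO, 14714809 for CAL27 with decitabine, 14830807 for SCC15 with DMSO and 17583706 for SCC15 with decitabine. A count of 0 was given a floor of 3 reads, which corresponds to 0.207, 0.204, 0.202 and 0.171 CPM in CAL27 DMSO, CAL27 decitabine, SCC15 DMSO and SCC15 decitabine. Where a gene had 0 reads in a library, a fold was given as a lower bound against this floor, per library for treatment ratios and over a line's 2 libraries for line differences. Where it had 1 to 3 reads, the ratio is given with its exact conditional binomial 95% interval. No fold is given where both sides were at or under the floor.

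All tests used R 4.3.3, edgeR 4.0.16 and limma 3.58.1. Choices in this paragraph and the next were made before the data were examined. The effect of decitabine shared by both lines was tested with edgeR's quasi-likelihood F test on the deposited counts, with TMM scaling and a filter on low counts (filterByExpr on the treatment groups, minimum count 10, minimum total 15), which left 15427 genes. The model had terms for cell line and treatment. The cell line is then the replicate, and the pairing comes from the labels: each decitabine library was set against the DMSO library of its own line. Libraries of the same line correlated at r = 0.983 (CAL27) and 0.961 (SCC15) on log2 CPM across genes, and the highest correlation across lines was 0.695. The model leaves 1 residual degree of freedom per gene, which holds the difference in response between the lines. The spread behind each p-value is moderated across genes (prior degrees of freedom 36.1, common biological coefficient of variation 0.234) and so comes mostly from other genes. The SE of a shared fold, derived from the fold and its F statistic, therefore does not measure how far the 2 lines differ for that gene. ICAM1, with log2 ratios of 0.37 and 3.82, had an SE of 0.46, and THBS1, with -1.15 and -1.10, had 0.29. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Such p-values speak of these 2 lines and of 1 culture of each. The difference between lines was tested in the same model. Within a line there is no test: genes were counted as higher or lower when the log2 ratio of TMM-scaled CPM, with a prior count of 2, was at least 1 in size and CPM was at least 1 in either library of the pair. The correlation of both lines' ratios is across genes with CPM of at least 1 in 2 libraries, and genes are not independent replicates, so it has no p.

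The 28 gene lists were fixed before the data were examined. They were tested with limma's camera on voom values with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. The correlation was estimated from 1 residual degree of freedom per gene, so that alternative could hardly call any list here. With the preset correlation, the genes of a list count as nearly independent, so that p does not measure the spread between lines or cultures. Camera compares a list with other genes, fry tests whether a list's genes move on balance 1 way, and its mixed p whether they move in either direction. As a description of the libraries, each list's median ratio was placed among 10000 random lists of the same size matched on mean expression (20 bins), and again matched also on transcript GC (5 bins). BAGE and IGF2AS had no match in the table (55 of 56 cancer-testis and 28 of 29 imprinted genes matched). The genes named follow a rule fixed in the same way. They are the 10 higher and 10 lower genes with the largest ratio in their weaker line among genes past the threshold with the same sign in both lines and at least 30 reads in the higher library of each line, with further genes given as values where fewer than 10 passed. DNMT1, DNMT3A, DNMT3B and UHRF1 were always named, as were up to 4 members of each list with the largest shared change. The rule also takes up to 5 genes each way with the largest difference between lines among those changed 2-fold in opposite directions, and 8 genes each way with the largest line difference and at least 100 reads. Unnamed loci were skipped, and results for some genes that the rule would name are not reported here. Genes named outside the rule are marked as chosen after their values were seen.

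The alternatives were RLE and total-count scaling, no filter, a filter of 30 reads in 2 libraries, DESeq2 1.42.0, the model without the cell line block, and limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1). For named genes each line was also left out in turn, which leaves the other line's ratio with no test. For ratios they were a prior count of 0.5, a CPM minimum of 5 and a 4-fold rule. Removal of the trend of each line's ratio with transcript GC (loess, span 0.5) and omission of mitochondrial genes with their nuclear copies were added after seeing the data. Scaling by total counts put the median ratio of all tested genes at 0.13 in CAL27 and 0.08 in SCC15, against 0 and 0.06 with TMM scaling, and changes are reported relative to the TMM scale. In data simulated from the library means for the shared test (14845 genes run), 20 of 100 genes changed 2-fold and 92 of 100 changed 4-fold were recovered, and 1 unchanged gene was called. The changed genes were drawn from the more highly expressed genes alone, with the same fold in both lines and no GC trend. Recovery of genes with few reads was not simulated. Counting error alone, simulated for the 2-fold rule, gave 30 genes higher and 34 lower in CAL27, and 33 higher and 23 lower in SCC15.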

Results

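The response of oral squamous carcinoma cells to the demethylating drug decitabine was measured by RNA sequencing in CAL27, a line from a tongue carcinoma, and in SCC15, also catalogued as a line from a tongue carcinoma. The stated aim was to find genes whose expression differs after the drug. The counted reads numbered 14524461 for CAL27 with DMSO, 14714809 for CAL27 with decitabine, 14830807 for SCC15 with DMSO and 17583706 for SCC15 with decitabine. At least 10 reads were counted for 14403, 15192, 13978 and 14478 genes in that order. Each group had 1 library, so no value below has a replicate of its own culture, and the replicate of the treatment is the other cell line. The libraries labelled SCC15 lacked many squamous epithelial transcripts, as described with the line comparison, and are called by their label throughout.

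With decitabine, 84 genes were higher and 12 were lower across both lines by edgeR's quasi-likelihood test at an adjusted p of 0.05, of 15427 genes tested. All 84 higher genes were at least 2-fold higher in the fit. Of these, 81 had a positive ratio in both lines, and the other 3 (among them ADAMTS9 and JPH4, named after their values were seen) had 0 reads in both CAL27 libraries, so that their call rests on the SCC15 pair alone. At an unadjusted p of 0.05, 1200 genes were higher and 397 lower. Without any effect, a share of about 0.05 of the 15427 genes would pass. The 397 lower genes are close to an even split of that number by direction. The call depends on the pairing by line: without the cell line block 0 genes passed in either direction, with 20 higher and 3 lower at an unadjusted p of 0.05, while DESeq2 called 27 higher and 13 lower. Total-count scaling gave 313 higher and 21 lower, no filter on low counts 155 and 21, and limma on log2(FPKM + 1) 1 and 1.

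Among higher genes with at least 30 reads in the higher library of each line, the largest change in the weaker line was that of H19 (ENSG00000130600, chromosome 11, 1995176 to 2001470), an imprinted noncoding RNA gene next to IGF2. It went from 3 to 44 reads in CAL27, a log2 ratio of 3.08 with a counting interval of 2.08 to 6.05, and from 0 to 205 reads in SCC15, at least 57-fold higher (adjusted p = 0.000738). CCL20 (ENSG00000115009, chromosome 2, 227805739 to 227817564), a chemokine that attracts CCR6-bearing lymphocytes, rose from 107 to 612 reads in CAL27, a log2 ratio of 2.34. In SCC15 it went from 1 to 154 reads, a log2 ratio of 5.53 with a counting interval of 4.51 to 12.32 (adjusted p = 0.000738).

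AGR2 (ENSG00000106541, chromosome 7, 16791811 to 16833433), a disulfide isomerase of mucus-secreting cells, had a shared log2 fold change of 2.43 ± 0.47 (SE of the fit moderated across genes, adjusted p = 0.00554). MUC1 (ENSG00000185499, chromosome 1, 155185824 to 155192916), a membrane mucin, rose by 2.26 ± 0.45 (adjusted p = 0.00802). SCNN1A (ENSG00000111319, chromosome 12, 6346843 to 6377730), a subunit of the epithelial sodium channel, rose by 2.36 ± 0.37 (adjusted p = 0.00113), from 181 to 727 reads in CAL27 and from 39 to 363 in SCC15.

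The receptor gene NOTCH3 (ENSG00000074181, chromosome 19, 15159038 to 15200981) rose by 2.14 ± 0.37 (adjusted p = 0.00237), with log2 ratios of 1.87 in CAL27 and 2.38 in SCC15. CEBPD, a transcription factor induced in inflammation (chromosome 8, 47736909 to 47739086), rose by 1.93 ± 0.38 (adjusted p = 0.0067). The guidance molecule SEMA5A (chromosome 5, 9035026 to 9546075) rose by 2.01 ± 0.45 (adjusted p = 0.0205). SYT12, a synaptotagmin (chromosome 11, 67006778 to 67050863), and ATP2A3, an endoplasmic reticulum calcium pump (chromosome 17, 3923870 to 3964464), rose by 2.25 ± 0.47 and 2.04 ± 0.48 (adjusted p = 0.0132 and 0.0316). Once the trend with transcript GC had been removed, 7 of these 10 genes passed the threshold and MUC1, ATP2A3 and CEBPD, at 1.80 ± 0.41, 1.60 ± 0.45 and 1.43 ± 0.34, did not. As for the other calls of single genes given below as ended, except those of IL1B and the mitochondrial genes, the fold shrank by a larger share than its SE. DESeq2 called 5 of the 10, without AGR2, SYT12, MUC1, ATP2A3 and SEMA5A, limma on log2(FPKM + 1) called CCL20 alone, and limma on log2(FPKM + 0.1) called 8, without ATP2A3 and SEMA5A.

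**Figure D1:**
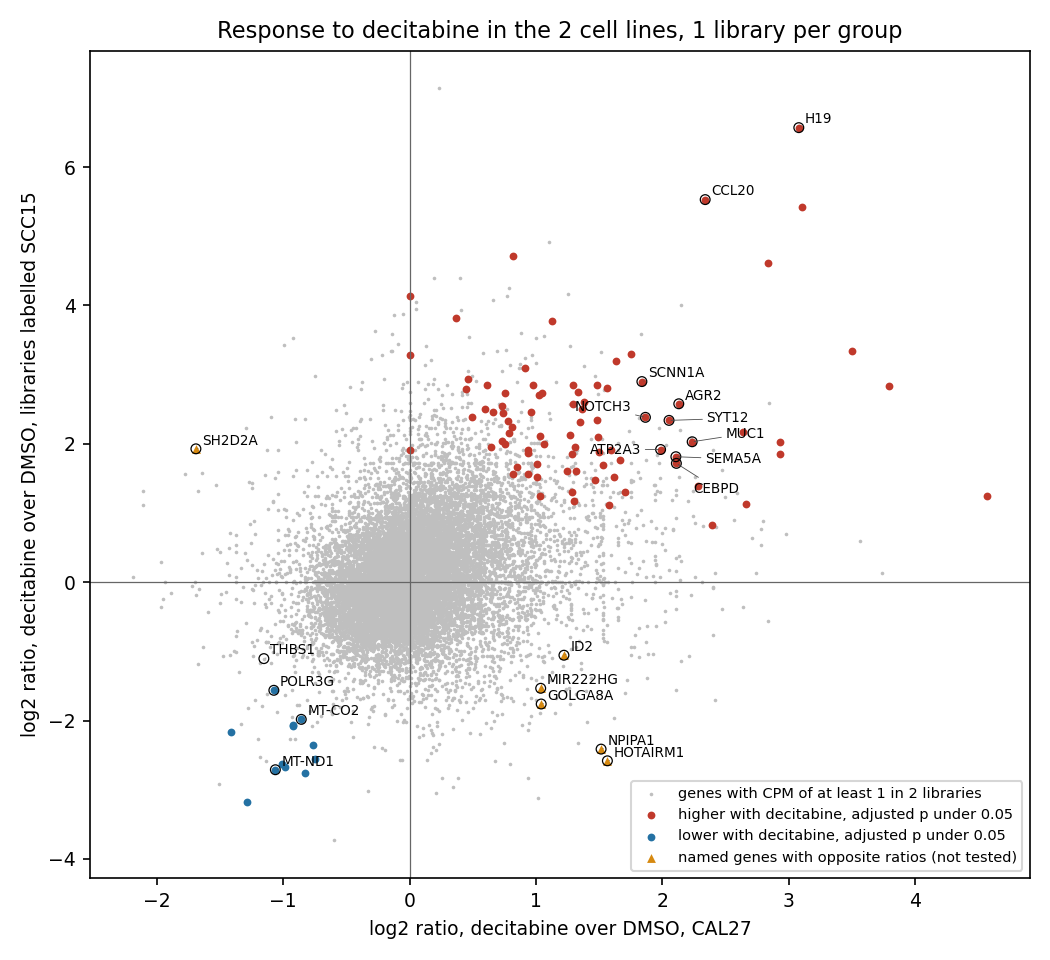
Each point is a gene, with the log2 ratio of decitabine over DMSO in CAL27 on the horizontal axis and in the libraries labelled SCC15 on the vertical axis, from 1 library per group. Grey points are genes with CPM of at least 1 in 2 libraries, red and blue points are all genes past the threshold of the shared test (84 higher, 12 lower), orange triangles are named genes with opposite ratios, and circled points carry the gene's name.

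Of the 12 lower genes, 8 were protein-coding genes of the mitochondrial genome and 3 were nuclear copies of such genes (MTND2P28, MTCO1P12 and MTATP6P1, named after their values were seen, with reads that counting may share with the mitochondrial originals). MT-ND1, a subunit of respiratory complex I (positions 3307 to 4262 of the mitochondrial genome), fell by 1.89 ± 0.34 on the log2 scale (adjusted p = 0.00366), with ratios of -1.06 in CAL27 and -2.71 in SCC15. MT-CO1, a subunit of cytochrome c oxidase (positions 5904 to 7445), fell by 1.82 ± 0.35 (adjusted p = 0.00554). MT-ND2 (positions 4470 to 5511) fell by 1.83 ± 0.34 (adjusted p = 0.00498). MT-CO2, MT-CO3, MT-CYB, MT-ND4 and MT-ATP6 were the other mitochondrial genes called. The share of reads in mitochondrially encoded genes went from 7.24% (exact 95% interval 7.23 to 7.26) to 4.28% (4.27 to 4.29) in CAL27, and from 7.6% (7.59 to 7.61) to 1.52% (1.52 to 1.53) in SCC15. With the GC trend removed the MT-ND1 fold was -1.88 ± 0.41 and the MT-CO1 fold -1.77 ± 0.49. None of the 8 mitochondrial genes then passed the threshold, as the standard errors were larger while these folds stayed close, and limma on either FPKM scale called none of the 8.

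POLR3G, a subunit of RNA polymerase III found mostly in undifferentiated cells (ENSG00000113356, chromosome 5, 90471748 to 90514553), was the other lower gene. It fell by 1.32 ± 0.33 on the log2 scale (adjusted p = 0.045), with ratios of -1.07 in CAL27 and -1.56 in SCC15, and among the alternatives it passed with total-count scaling, no filter and the filter of 30 reads alone. With the GC trend removed its shared log2 fold was -0.95 ± 0.28. THBS1, which encodes the matrix protein thrombospondin, had ratios of -1.15 and -1.10 and did not pass (adjusted p = 0.0557).

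Transcripts of the drug's targets did not pass the test. DNMT1, the maintenance methyltransferase, had log2 ratios of -0.10 in CAL27 and 0.41 in SCC15 (adjusted p = 0.902), and UHRF1, which recruits it to replicating DNA, had -0.10 and 0.30 (adjusted p = 0.942). For both, the sign of the shared fold turned when the GC trend was removed. The de novo methyltransferases DNMT3A (0.65 and 0.75, adjusted p = 0.473) and DNMT3B (0.36 and 0.32, adjusted p = 0.81) were above 0 in both lines. Of the 15 tested genes of the methylation machinery, 0 passed, the list test gave adjusted p = 0.291, and the list's medians were -0.10 and 0.16. HELLS, a chromatin remodeller needed for methylation, had ratios of -0.39 and -1.14.

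The ratio of decitabine over DMSO moved with the GC content of the transcript, and more so in SCC15. Across 14452 genes, Spearman's rho of the ratio with GC was 0.261 in CAL27 and 0.517 in SCC15. From the lowest to the highest decile of genes by GC, the median log2 ratio went from -0.10 to 0.23 in CAL27 and from -0.50 to 0.58 in SCC15. The counts of calls moved with this trend: with it removed, 27 genes were higher, all of them among the 84, and 3 were lower (MTND2P28, MTCO1P12 and GAL, the last chosen after its value was seen).

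**Figure D2:**
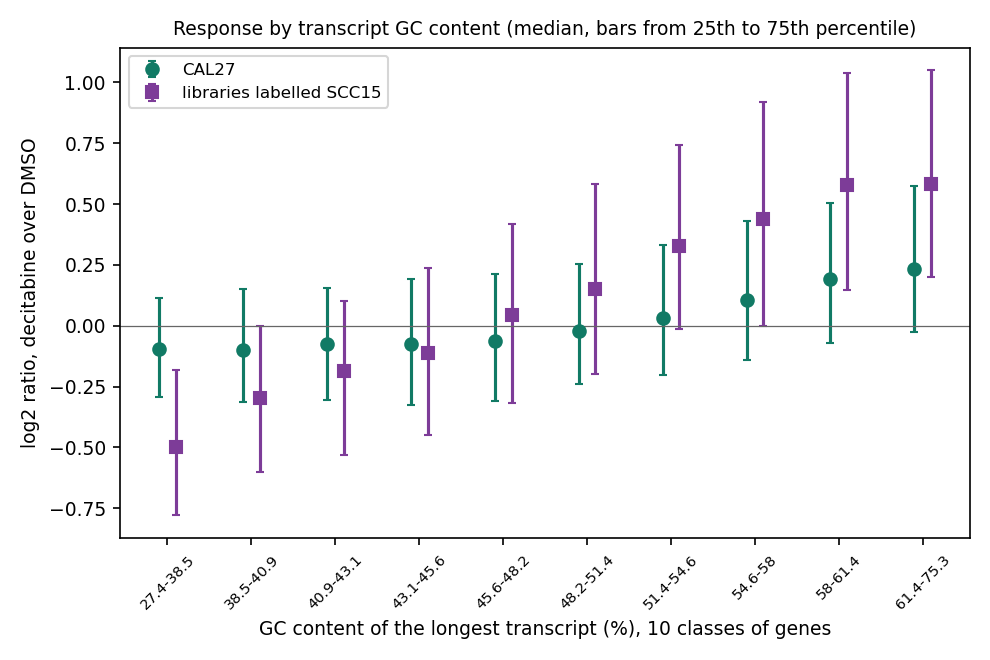
Median log2 ratio of decitabine over DMSO (vertical axis) by decile of genes ordered by transcript GC content in percent (horizontal axis), for CAL27 and for the libraries labelled SCC15. The medians go from -0.10 to 0.23 in CAL27 and from -0.50 to 0.58 in SCC15, and bars span the middle of the genes in each decile (25th to 75th percentile).

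Cytokine and NF-kB target genes rose as a list, with the smallest p of the 11 lists called higher. Camera gave adjusted p = 1.19e-11, and adjusted p = 0.523 with an estimated correlation, the upper end of a range from 2.02e-14 over the alternatives. Fry gave adjusted p = 0.0928. Of its 28 tested members, 8 rose over all genes tested and 19 when adjusted over the list alone, none fell, and 20 had positive ratios in both lines. The list's median log2 ratio was 0.62 in CAL27 and 1.67 in SCC15, at percentile 100 of random lists in each line, also among lists matched on GC. CXCL5, a neutrophil-attracting chemokine, went from 0 to 13 reads in CAL27 and from 0 to 51 in SCC15 (at least 3.89-fold and at least 14.2-fold higher, adjusted p = 0.0139). With 0 reads in both DMSO libraries, CXCL5 passed the filter through its decitabine reads alone and could only come out higher. IL1B, the gene of interleukin 1 beta, went from 2082 to 4084 reads in CAL27 and from 1 to 87 in SCC15 (adjusted p = 0.04). ICAM1, a leukocyte adhesion molecule, had ratios of 0.37 and 3.82 (adjusted p = 0.0318), and CCL20 is given above. With the GC trend removed the calls of CXCL5 and CCL20 held and those of IL1B and ICAM1 ended, where the shared log2 fold went from 1.82 ± 0.44 to 1.81 ± 0.45 for IL1B and from 1.92 ± 0.46 to 1.62 ± 0.45 for ICAM1. The IL1B fold and SE hardly moved, and the call was close to the threshold before.

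Interferon-stimulated genes were called higher as a list by camera with the preset correlation (adjusted p = 8.05e-06; with an estimated correlation adjusted p = 0.523, in a range from 3.62e-08 over the alternatives). Of the 43 tested, 1 passed over all genes and 6 when adjusted over the list alone. Their medians were 0.31 in CAL27 and 0.87 in SCC15, and 32 members were positive in both lines and 3 negative in both. BST2, the membrane protein tetherin that retains enveloped virus particles, rose by 1.91 ± 0.45 (adjusted p = 0.0275), and by 1.63 ± 0.41 with the GC trend removed, where it did not pass. The chemokine gene CXCL10 went from 2 to 17 and from 20 to 118 reads (adjusted p = 0.117), and CXCL11 had ratios of 0.63 and 1.85. Antigen processing and presentation genes were called as a list (adjusted p = 0.00097; with an estimated correlation adjusted p = 0.523, in a range from 0.000385), while 0 of 23 members passed. Their medians were 0.30 and 0.63, or 0.70 in SCC15 with genes at 0 reads set to their bound. With the GC trend removed the medians were 0.17 in CAL27 and 0.24 in SCC15, and camera still called the list (adjusted p = 0.00369). The class II genes HLA-DRA, HLA-DPA1 and HLA-DPB1 had CAL27 ratios of 1.01, 1.62 and 1.05 and 0 reads in both SCC15 libraries. Genes that sense double-stranded RNA were not called (adjusted p = 0.291, 0 of 14 members), with DHX58 at 0.97 in CAL27 and from 1 to 9 reads in SCC15.

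Germline genes and cancer-testis antigens are silenced by methylation in most somatic cells. DAZL, an RNA-binding protein of germ cells (chromosome 3, 16586792 to 16670306), went from 0 to 16 reads in CAL27 and from 0 to 91 in SCC15, at least 4.79-fold and at least 25.3-fold higher (adjusted p = 0.00269). It was the only gene of 14 tested germline and meiosis genes to pass, and the list was not called (adjusted p = 0.291, medians 0.34 and -0.08, or 0.53 and 0.15 with genes at 0 reads set to their bound). Cancer-testis antigens were called higher as a list (adjusted p = 0.0122; with an estimated correlation adjusted p = 0.523, in a range from 0.012 over the alternatives) with medians of 0.57 and 0.58. Of 55 matched members, 12 had enough reads to be tested, and their shared log2 folds had a mean of 1.52 and a median of 0.54. None of these 12 passed over all genes and 4 did when adjusted over the list alone. The CTCF paralogue CTCFL went from 0 to 11 and from 0 to 21 reads, and MAGEC1 from 0 to 11 and from 0 to 15. Like DAZL, both had 0 reads with DMSO in either line. They passed the filter through their decitabine reads alone and could only come out higher. MAGEA4 was present in CAL27 before treatment (3896 and 5097 reads) and went from 0 to 305 reads in SCC15, at least 84.8-fold higher. MAGEB2 had the opposite layout, with 0 and 26 reads in CAL27 and 1570 and 2058 in SCC15. The call of this list was lost when members needed 30 reads in 2 libraries.

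Imprinted genes were not called as a list (adjusted p = 0.291, 1 of 18 members, H19), with medians of 0.20 and 0.17, and CDKN1C, a cell cycle inhibitor, had ratios of 0.52 and 0.72. Genes reported as methylated in oral and head and neck carcinoma were not called either (adjusted p = 0.14, medians 0.16 and 0.27, or 0.50 in SCC15 at the bound). Of its 35 tested members 0 passed over all genes, while 4 were higher and 1 lower when adjusted over the list alone. TFPI2, a protease inhibitor, went from 4 to 27 reads in CAL27 and from 0 to 33 in SCC15, at least 9.18-fold higher there. The Wnt antagonist SFRP1 went from 9 to 24 and from 0 to 64 reads, at least 17.8-fold higher in SCC15.

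**Figure D3:**
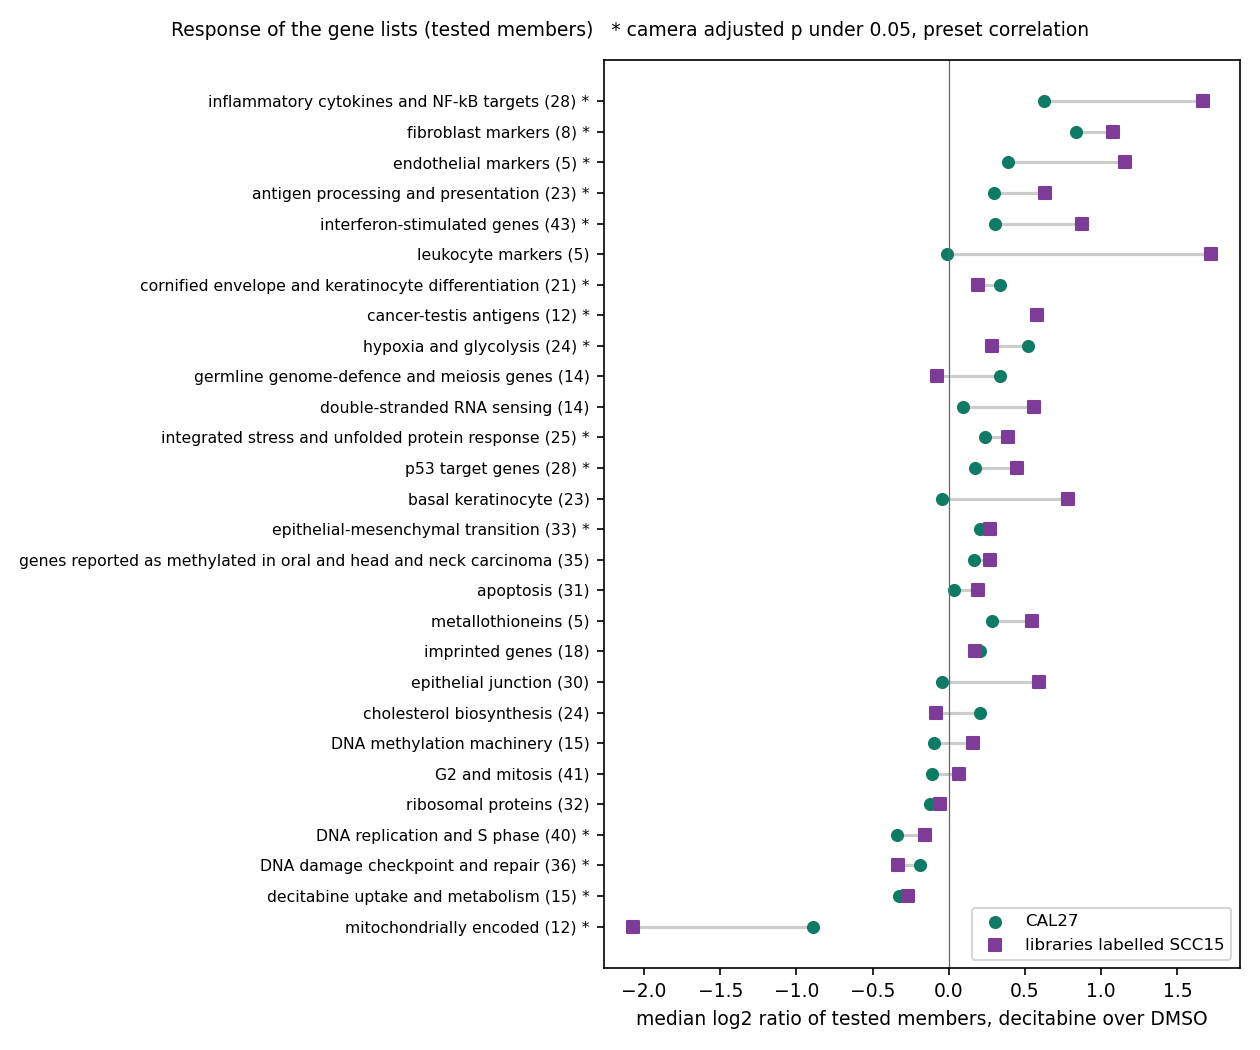
Median log2 ratio of decitabine over DMSO (horizontal axis) of each of the 28 gene lists (vertical axis) in CAL27 and in the libraries labelled SCC15, joined by a line, with the number of tested members in brackets and an asterisk for an adjusted p under 0.05 by camera with the preset correlation. The mitochondrially encoded genes lie lowest, at -0.89 and -2.07, and cytokine and NF-kB target genes at 0.62 and 1.67.

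DNA replication genes were lower as a list (adjusted p = 3.5e-05; with an estimated correlation adjusted p = 0.553, in a range from 9.78e-08), with medians of -0.34 in CAL27 and -0.15 in SCC15 and 23 of 40 members negative in both lines and 0 positive in both, although 0 passed alone. PRIM1, a primase subunit, had ratios of -0.84 and -0.80. DNA damage and repair genes were also lower (adjusted p = 0.000883; with an estimated correlation adjusted p = 0.523, in a range from 0.000583), with medians of -0.19 and -0.33 and 0 of 36 members called. The end-resection factor RBBP8 had -0.70 and -0.96. G2 and mitosis genes were not called (adjusted p = 0.344, medians -0.11 and 0.07, 0 of 41). Genes of decitabine uptake and metabolism were lower as a list (adjusted p = 0.0391; with an estimated correlation adjusted p = 0.523, in a range from 0.019). Their medians were -0.33 and -0.27, 0 of 15 passed, the kinase gene CMPK1 had -0.47 and -0.66, and the call was lost when members needed 30 reads in 2 libraries.

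Targets of p53 were higher as a list (adjusted p = 0.0192; with an estimated correlation adjusted p = 0.523, in a range from 0.0154), with medians of 0.17 and 0.45, and 3 of 28 members rose. These were CDKN1A, the cell cycle inhibitor p21 (ratios 0.74 and 2.45, adjusted p = 0.0178), the stress cytokine GDF15 (1.62 and 1.53, adjusted p = 0.00554) and TP53I11 (1.53 and 1.70, adjusted p = 0.0263), and all 3 calls ended with the GC trend removed. The shared log2 folds then went from 1.57 ± 0.34 to 1.26 ± 0.30 for CDKN1A, from 1.58 ± 0.31 to 1.20 ± 0.26 for GDF15 and from 1.63 ± 0.38 to 1.30 ± 0.33 for TP53I11. Apoptosis genes were not called (adjusted p = 0.252, 0 of 31), with BMF at 1.48 and 0.79. Integrated stress and unfolded protein response genes were called higher (adjusted p = 0.0205; with an estimated correlation adjusted p = 0.523, in a range from 0.0144) with 0 of 25 members past the threshold, medians of 0.23 and 0.39, and DDIT4 at 0.71 and 1.14. Their SCC15 median went from percentile 97.1 to 84.8 when random lists were matched on GC.

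Hypoxia and glycolysis genes were higher as a list (adjusted p = 0.000112; with an estimated correlation adjusted p = 0.523, in a range from 3.89e-05), with medians of 0.52 in CAL27 and 0.28 in SCC15. Of 24 members, 2 rose over all genes and 6 when adjusted over the list alone. NDRG1, a growth-arrest gene, rose by 1.36 ± 0.29 (adjusted p = 0.016), and ANGPTL4, a regulator of lipoprotein lipase, by 1.79 ± 0.40 (adjusted p = 0.0195). The ratios of NDRG1 were 1.58 in CAL27 and 1.12 in SCC15 and those of ANGPTL4 2.66 and 1.13, and the ANGPTL4 call ended with the GC trend removed, at a shared log2 fold of 1.34 ± 0.37. Cholesterol biosynthesis (adjusted p = 0.773, medians 0.20 and -0.09) and ribosomal protein genes (adjusted p = 0.11, medians -0.12 and -0.06) were not called, the latter becoming called lower with the GC trend removed. Metallothionein genes were not called (adjusted p = 0.476, 5 tested), and their SCC15 median of 0.55 was -0.43 when genes at 0 reads were set to their bound and genes under the floor left out. The mitochondrially encoded list had adjusted p = 1.91e-20, with an estimated correlation adjusted p = 0.523 and a range from 1.78e-26, and 12 of its 12 tested members were lower when adjusted over the list alone.

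Among differentiation lists, cornified envelope genes were higher (adjusted p = 0.00148; with an estimated correlation adjusted p = 0.553, in a range from 2.91e-05). Of 21 tested members, 1 rose over all genes (PPL, the desmosomal linker periplakin, chosen after its value was seen) and 5 when adjusted over the list alone. S100A9, a calcium-binding alarmin, went from 74 to 419 reads in CAL27 and had 0 in both SCC15 libraries, and PADI3 went from 59 to 295 and from 2 to 11. Many of these genes were at or under the floor in SCC15, where the median was 0.19, or 0.81 over the 13 members that could be given a ratio or bound. That SCC15 median went from percentile 75.4 to 25.9 when random lists were matched on GC, and was 0.004 with the GC trend removed. Basal keratinocyte genes (adjusted p = 0.0727, medians -0.05 and 0.78, or 1.12 in SCC15 at the bound) were not called, but were with total-count scaling. Epithelial junction genes (adjusted p = 0.328) were not called either, with 1 of 30 members, the plakoglobin gene JUP, rising by 1.51 ± 0.34 (adjusted p = 0.0212). The JUP ratios were 0.66 in CAL27 and 2.46 in SCC15, and the calls of JUP and PPL ended with the GC trend removed, at shared log2 folds of 1.14 ± 0.32 and 0.94 ± 0.28 (PPL 1.28 ± 0.31 before).

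Genes of epithelial-mesenchymal transition were called higher (adjusted p = 0.0442; with an estimated correlation adjusted p = 0.523, in a range from 0.00933), with medians of 0.20 and 0.27, or 0.33 in SCC15 at the bound. Of 33 members, MMP14, a membrane-anchored collagenase, rose by 1.41 ± 0.35 (adjusted p = 0.045), with ratios of 0.60 in CAL27 and 2.51 in SCC15 and a call that ended with the GC trend removed, at a shared log2 fold of 1.08 ± 0.32. The list's call was lost when members needed 30 reads or mitochondrial genes were left out. Markers of cell types not expected in a carcinoma line were tested as well. Fibroblast markers were called higher (adjusted p = 3.5e-05; with an estimated correlation adjusted p = 0.523, in a range from 1.37e-05), with medians of 0.83 and 1.08, or 1.28 in CAL27 at the bound. Of its 8 tested members, the collagen gene COL1A1 rose by 2.13 ± 0.39 (adjusted p = 0.00435), from 202 to 669 and from 20 to 181 reads (ratios 1.56 and 2.81), and 5 passed when adjusted over the list alone. Endothelial markers were called higher (adjusted p = 0.0172; with an estimated correlation adjusted p = 0.523, in a range from 0.0178 over the alternatives) with 5 tested members, 0 of them past the threshold, mostly at low counts (PECAM1 0 and 3 reads in CAL27, 11 and 32 in SCC15), and this call was lost when members needed 30 reads. Leukocyte markers were not called (adjusted p = 0.0805, 5 tested), with CD14 from 16 to 46 and from 4 to 72 reads. None of the 15 called lists passed with an estimated correlation or with fry, and fry's mixed test passed for hypoxia and glycolysis genes alone (adjusted p = 0.0218). With the estimated correlation, camera's smallest p before adjustment was 0.0625. It was that of the mitochondrially encoded list, whose 12 tested members were all negative in both lines. At 1 residual degree of freedom per gene that alternative could hardly call a list, so it does not decide for or against any of them. The preset correlation takes genes as nearly independent, so the list calls do not speak of agreement between the lines or of other cultures. DESeq2 did not call the list members CDKN1A, TP53I11, BST2, ICAM1, IL1B, ANGPTL4, JUP and MMP14, RLE scaling did not call IL1B and MMP14, and limma on log2(FPKM + 0.1) did not call TP53I11, NDRG1 and MMP14.

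Within CAL27, 575 genes were at least 2-fold higher and 147 lower with decitabine, and with total-count scaling 830 and 96. Within SCC15, 1647 were higher and 784 lower. With the GC trend removed the counts were 463 higher and 191 lower in CAL27, and 1106 and 616 in SCC15. These are counts by size with no test. Of 12460 genes measured in both lines, 164 were 2-fold higher in both where independent lists would share 45.2, and 27 were lower in both where 5.1 would be shared. Higher in both were 50 (9.1 for independent lists) at a CPM minimum of 5, 31 (4.5) on log2(FPKM + 1) and 105 (23.7) with the GC trend removed, and lower in both were 8 (0.9) and 3 (0.1) in the first and second of these settings. The ratios of both lines correlated across 14452 genes at Pearson's r = 0.258 and Spearman's rho = 0.272, and at 0.177 and 0.175 with the GC trend removed. Another 37 genes were changed 2-fold in opposite directions, beside 32.3 for independent lists, with 2 (5.8) at a CPM minimum of 5, 3 (1.7) on log2(FPKM + 1) and 39 (22.2) with the GC trend removed.

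The lines were compared with each other as the background of the treatment comparison. At an adjusted p of 0.05, 3496 genes were higher in CAL27 and 3329 higher in SCC15. KRT5, the basal keratin (chromosome 12, 52514575 to 52520687), had 8054 and 8359 reads in CAL27 and 0 and 1 in SCC15, a ratio of read shares of 16400 with a counting interval of 2940 to 648000. LAD1, a basement membrane anchoring protein, and PRSS8, the epithelial protease prostasin, were at least 903-fold and at least 805-fold higher in CAL27. NLRP2, BASP1, IRX2 and HSPA13 were at least 1050-fold, 987-fold, 967-fold and 941-fold higher. Of 30 epithelial junction genes, 26 were higher in CAL27 and 0 in SCC15, and of 23 antigen presentation genes 23 were higher in CAL27.

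Among genes higher in SCC15, CPLX2, a regulator of vesicle fusion (chromosome 5, 175796310 to 175884020), had 0 reads in both CAL27 libraries and was at least 2440-fold higher in SCC15, and CHGA, the granule protein chromogranin A (chromosome 14, 92923080 to 92935293), was at least 1160-fold higher. PEG10, a retrotransposon-derived imprinted gene (chromosome 7, 94656325 to 94669695), had 0 and 6 reads in CAL27 and 12029 and 18758 in SCC15. FOXR1, TM4SF18, ADAMTS9, PNMA2 and IGFBP2 had 0 reads in both CAL27 libraries and were at least 1160-fold, 886-fold, 684-fold, 558-fold and 395-fold higher in SCC15. Of genes at 10 CPM or more in the other line's DMSO library, 64 had 0 reads in both SCC15 libraries and 45 had 0 in both CAL27 libraries. All 15 genes named here passed the edgeR test, with adjusted p of 2.85e-15 or smaller.

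**Figure D4:**
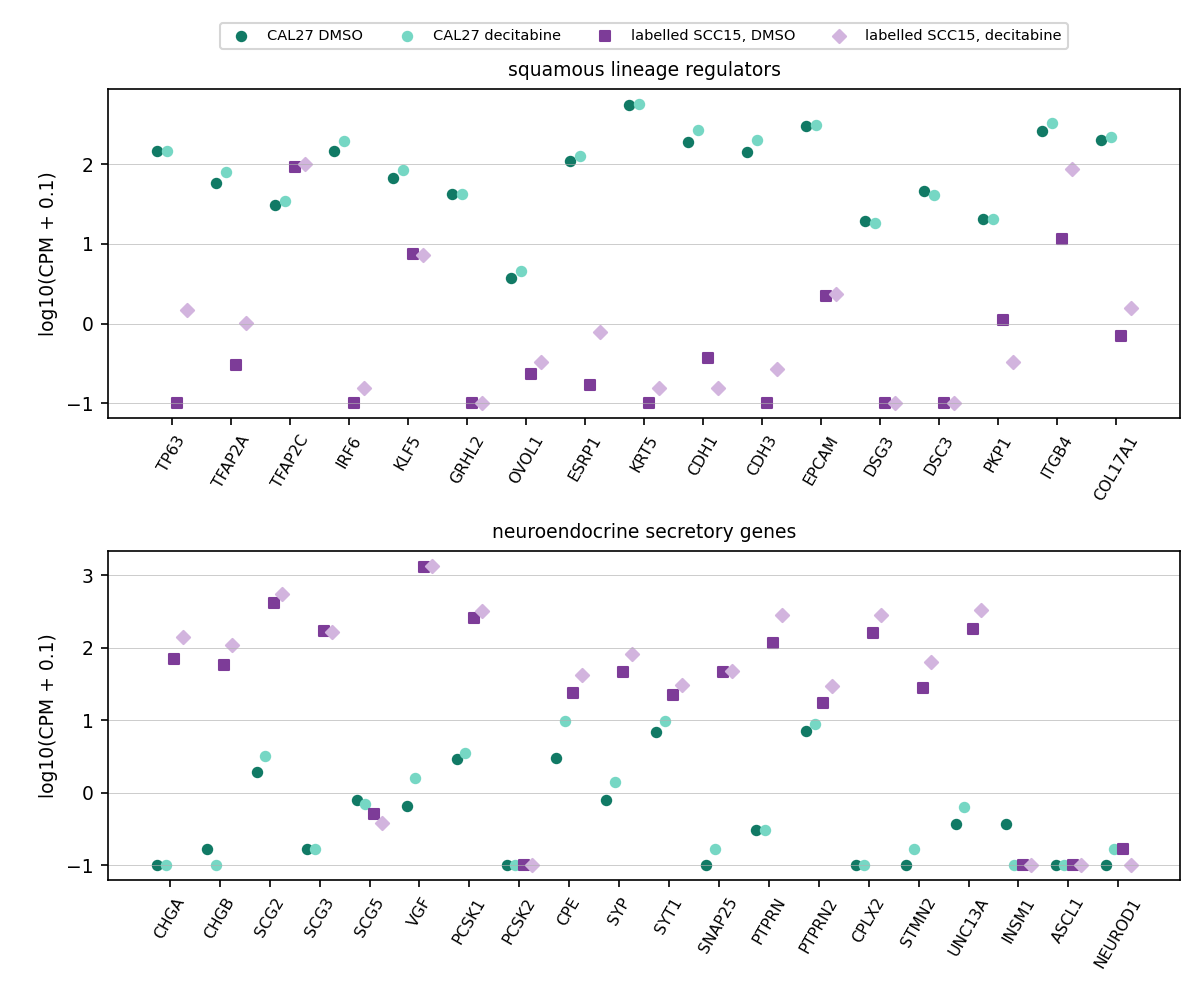
Expression as log10(CPM + 0.1) on the vertical axis for squamous lineage regulators and neuroendocrine secretory genes on the horizontal axis, 1 point for each of the 4 libraries; both sets were written after the leading line differences were seen. At 1 CPM or more were 17 of 17 squamous genes in both CAL27 libraries and 5 and 6 in the SCC15 libraries, while of 20 neuroendocrine genes 5 and 7 reached it in CAL27 and 15 in each SCC15 library.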

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

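Of the tests in this part, that of expression level for the GC trend was fixed before its result was seen, and the tests on length, library preparation, mitochondrial transcripts and the SCC15 label were chosen after the results were seen.

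Some genes moved in opposite directions in the 2 lines, and these differences were not tested, since each group had 1 library. HOTAIRM1, a noncoding RNA of the HOXA cluster, had log2 ratios of 1.57 in CAL27 and -2.58 in SCC15, a difference of 4.15. NPIPA1 (1.52 and -2.41, a difference of 3.93) and GOLGA8A (1.04 and -1.76, a difference of 2.80) belong to multi-copy families whose counts are uncertain. MIR222HG, a microRNA host gene, had 1.04 and -1.53, a difference of 2.57. With the GC trend removed its ratios were 1.095 and -0.96, the latter short of 2-fold. ID2, an inhibitor of helix-loop-helix transcription factors, had 1.22 and -1.06, a difference of 2.28. SH2D2A, a T cell adaptor, had -1.69 and 1.93, a difference of -3.62, and was the only gene to meet the naming rule in that direction. On log2(FPKM + 1), 8 of the ratios of these named genes moved outside their counting intervals and 4 did not, and none changed sign. In all 37 genes were changed 2-fold in opposite directions, 32 of them higher in CAL27 and 5 higher in SCC15. Independent lists would give 32.3, and the count was 2 (5.8 for independent lists) at a CPM minimum of 5, 3 (1.7) on log2(FPKM + 1) and 39 (22.2) with the GC trend removed.

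The ratio of decitabine over DMSO rose with transcript GC content, most in SCC15. Re-expression of silenced GC-rich genes was weighed against this, which requires the trend to sit in genes that were low before treatment, but rho was 0.649 among SCC15 genes above the median of DMSO expression, so it does not explain the trend in SCC15 as a whole. Transcript length is also excluded as the whole cause in SCC15, since rho there had a median of 0.587 within 10 length classes. In CAL27 the weaker trend had a median rho of 0.246 within length classes, beside 0.261 over all genes. Above the median of expression rho was 0.297 in CAL27, and below it 0.201. The limits set for these tests concerned SCC15, and the CAL27 values fell short of them, so by that rule they decide neither cause in CAL27. They show a CAL27 trend nearly as strong within length classes, and no weaker above the median of expression than below it. GC bias of library preparation or sequencing could account for it: in SCC15 the trend was present above and below the median of expression, with the smaller rho 0.394, and in CAL27 the smaller was 0.201. With 1 library per group such a bias and a true shift towards GC-rich transcripts after decitabine cannot be told apart.

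Mitochondrially encoded transcripts were lower with decitabine in both lines. The GC trend leaves a median log2 ratio of -0.869 in CAL27, the line with the smaller fall, once it is removed, so it is not the whole cause, although the gene-level calls ended because the standard errors grew. Scaled on nuclear genes alone, the median was -0.891 in CAL27 and -2.07 in SCC15, beside -0.89 and -2.07 with the main scaling. The fall thus did not depend on mitochondrial genes being in the scaling. TMM already trims genes with extreme ratios or abundance, so this test could hardly come out otherwise. It does not decide on scaling distorted by abundant genes. Reads moved to nuclear pseudogene copies would leave the summed share unchanged, but it fell by 0.756 and 2.32 on the log2 scale. An effect of decitabine, or of differences between cultures or RNA preparations with 1 library per group, remains open and untested.

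The libraries labelled SCC15 lacked many squamous epithelial transcripts, though 5 of 17 regulators reached 1 CPM in the DMSO library, TFAP2C at 90.4 CPM beside 30.5 in CAL27. Too little depth is excluded, since the least abundant in CAL27 of the regulators at or under 3 reads (OVOL1) would have 54.12 reads at its CAL27 level. A single mislabelled library is excluded as well, since the libraries of this label correlated at r = 0.961 and the highest correlation across lines was 0.695. A cell line other than a squamous carcinoma line under the SCC15 label may be a candidate explanation, as 15 of 20 neuroendocrine secretory genes, a list written after the line differences were seen, reached 1 CPM in the DMSO library, with VGF at 1303 CPM, SCG2 at 406.7 and PCSK1 at 258.6 the most abundant, while 5 of the 20 also reached it in CAL27. No reference profile of SCC15 was used here, so this and an unusual state of SCC15 itself cannot be told apart.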

How the results depend on the processing

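Removal of the GC trend and omission of mitochondrial genes were chosen after seeing the data. Where an alternative has no cause given below, the cause was not tested. The counts of genes differing between lines stayed within 1.5 times under every alternative run (2618 to 4242 higher in CAL27, 2543 to 3563 higher in SCC15). Genes higher with decitabine (84) numbered 313 with total-count scaling, 155 with no filter, 27 with DESeq2, 0 with no cell line (replicate) block, 1 on log2(FPKM + 1) and 27 with the GC trend removed, and genes lower (12) numbered 21, 21, 13, 0, 1 and 3 in that order and 1 without mitochondrial genes, where by construction the called mitochondrial genes are gone. All of the 84 were called with total-count scaling and with no filter. Within lines, 2-fold counts (higher and lower) at a CPM minimum of 5 were 193 and 41 in CAL27, and 422 lower in SCC15. On log2(FPKM + 1) they were 125 and 13, and 646 and 194. With a 4-fold rule, stricter by construction, they were 55 and 5, and 278 and 90. With total-count scaling 96 were lower in CAL27. Genes higher in both lines were 50 at CPM 5, 31 on log2(FPKM + 1) and 105 with the GC trend removed. Those lower in both were 8 and 3, and those opposite 2 and 3, at CPM 5 and on log2(FPKM + 1). Pearson's r of the ratios was 0.216 with a prior count of 0.5, 0.308 at CPM 5, 0.288 on log2(FPKM + 1) and 0.177 with the GC trend removed, and Spearman's rho 0.314 and 0.175 at CPM 5 and with the GC trend removed. Of the lists, 11 higher and 4 lower became 0 and 0 with an estimated correlation and 0 and 0 with fry. The estimate rested on 1 residual degree of freedom per gene, at which hardly any list could pass. Among alternatives that keep both lines, directions turned for uncalled results alone: G2 and mitosis with the GC trend removed (adjusted p = 0.599, range 0.33 to 0.796), cholesterol biosynthesis with members of 30 reads (0.956) and with the GC trend removed (0.903, range 0.763 to 0.956), and the shared log2 folds of DNMT1 (-0.086) and UHRF1 (-0.114) with the GC trend removed. Leaving out a line leaves the other line's ratio, with no test: without CAL27, 61 named treatment genes moved by more than the standard error of the shared fold and 67 did not, without SCC15 50 did and 78 did not, and no called gene among them changed sign. Uncalled genes could change sign, as DNMT1 and UHRF1 did without SCC15, at -0.10 each beside shared log2 folds of 0.155 and 0.101. Depth limits genes with 0 to 3 reads in a library, for which bounds or intervals alone are given, and at this design 20 of 100 simulated 2-fold changes in more highly expressed genes were recovered.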

Other observations

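The genes in this part, apart from CHGA and ITGB4, which the naming rule takes, were chosen after the data were seen. None of them passed the shared test of decitabine, and their changes within a line have no test. Some epithelial regulators at 0 to 3 reads in the SCC15 DMSO library had more reads with decitabine. TP63, the master regulator of squamous epithelium, had 0 and 24 reads in SCC15 beside 2133 and 2163 in CAL27. ESRP1, an epithelial splicing factor, had 1 and 12 reads in SCC15 beside 1581 and 1875 in CAL27, and TFAP2A had 3 and 16. The integrin gene ITGB4 went from 171 to 1512 reads (edgeR's adjusted p = 0.0735 for the shared effect). GRHL2, DSG3 and DSC3 had 0 reads in both SCC15 libraries. Among neuroendocrine secretory genes already present in SCC15, CHGA went from 70.1 to 138.1 CPM and PTPRN from 114.5 to 282.6 CPM, while VGF had 1303 and 1333 CPM. These CPM were scaled to library totals. On the TMM scale the SCC15 log2 ratio of CHGA was 0.96, and it was 0.46 with the GC trend removed.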
